A study of Penicillium expansum with 2 samples.

How the data were processed

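RNA was taken from spores of Penicillium expansum in 2 libraries, 1 treated with Meyerozyma guilliermondii and 1 control, prepared with the Illumina TruSeq RNA kit per the labels' protocols. The submitters' processing notes name Bowtie 0.12.2 and the build mm8, with no role. mm8 is a mouse build, while the feature identifiers in the deposited files are of the Trinity form, which is that of a de novo assembly; how the build was used is not given in the sources used here. The tool behind the fold changes and false discovery rates is not given either.

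The values used came from the authors' deposited table of T02 against T01. The authors gave log2 fold changes of T02 over T01, per the file headers. The authors also gave a false discovery rate, an adjusted p-value, per the file headers, and every listed feature was under 0.05. The expression table has 2 value columns, named T01 and T02, that match no sample label. They were not used in any step, although their totals and ranges were viewed when the file was first examined; only the 20514 identifiers were counted. All 427 listed features are among them. Coordinates are not given, since no build of this organism is named. Of 12 Penicillium locus tags in the best hits, 2 matched the RefSeq gene table of P. expansum strain MD-8.

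Read numbers were recovered from the fold changes, a step thought of after the data were seen. The folds took the values they would have if a prior count of 0.1305 in T01 and 0.1195 in T02 had been added to whole read numbers. For each feature the pair of whole numbers with at most 100 reads in the lower library was sought to within 0.0001 of a read. A pair was found for all 427 features, and it was the only pair for 424; for the other 3 the pair with the lowest count was taken. The tolerance was tightened after a looser one had let in false pairs. The read numbers may be rounded estimates, and the authors did not deposit them as counts. The ratio of the priors put the depth of T01 at 1.09 times that of T02, and ratios were scaled by it. The total depth of each library is not known from the values used. The search was tested on 20 simulated sets of 427 features; earlier forms of it failed this or an easier test and were replaced, and the values recovered from the deposited table stayed as they were. In the final form both priors came back in all 20 sets, and the lowest share of pairs recovered in a set was 99.766%. At most 3.5% of 400 random folds per set were given a pair. The simulated sets were drawn with the same form of prior count that the search assumes.

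Ratios of recovered reads have exact (Clopper-Pearson) 95% intervals, and a library without a read was set at a floor of 3 reads. Both cover counting error only. Shares of features have exact intervals over features, which are not independent replicates. Features were assigned to a source by the organism of the best hit: Penicillium or Aspergillus, any of the ascomycete yeast genera, or other. An assembly cluster is the part of an identifier before its last element.

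The labels give 1 library per group, so no test across samples was made and no p-value was computed. Several planned results were left out by choice, because the columns match no sample. These were the count of features differing by level, list medians among random lists, and the share of each library in yeast features. For the count by level, the plan was to describe such columns under their own names, T01 and T02, which was not done. The 28 gene lists were fixed as name patterns before the data were examined, and only counts and values are given for them. Named features were the 12 highest and 12 lowest by fold among those with an informative description, plus up to 4 per list. The planned minimum level was not applied. The atp-1 feature, the feature with a Medicago hit and both features of the assembly cluster that was lower in T02 fall outside this rule and were chosen after their values were seen. An enrichment was not computed, as unlisted features carry no annotation in the table used. Stricter thresholds, other yeast patterns and subsets by reads or clusters were tried as alternatives. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.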

Results

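The series holds 2 RNA sequencing libraries from spores of Penicillium expansum, the mould that causes blue mould of apples and pears and that makes the mycotoxin patulin. By the labels, 1 library came from spores treated with Meyerozyma guilliermondii, a yeast studied as a biological control agent, and 1 from control spores without it. Both cultures were kept in NYDB medium for 24 h at 25 °C and 120 rpm. The question the design asks is which transcripts differ in level between yeast-treated and control spores. There was 1 library per group, so no difference has a replicate check, and any test on 2 libraries compares those libraries and not the conditions.

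The authors' deposited table calls its libraries T01 and T02, and neither name matches the label of a sample. Directions are therefore given as T02 relative to T01 throughout, and none is given as treated relative to control. The table lists 427 assembled features, each with a log2 fold change of T02 over T01, a false discovery rate (FDR) and the best protein hits. It holds only features with an FDR under 0.05, so a gene that is missing from it is not shown to be unchanged. The expression table lists 20514 features, and its values were not used.

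Transcripts whose best protein hit was a yeast made up most of the difference. The authors' deposited table has 401 features higher in T02 and 26 lower. Of the 401 higher features, 368 had a yeast as the organism of their best hit, a share of 91.8% (exact 95% interval over features 88.6% to 94.3%). The named species was M. guilliermondii for 334 of them. No feature lower in T02 had a yeast best hit, and with 26 such features the exact interval reached 13.2%. Penicillium or Aspergillus was the source of 32 higher and all 26 lower features. The remaining higher feature had a best hit in the plant Medicago truncatula. Features with a yeast best hit are called yeast features below, for that hit only. Of the patterns of yeast genera fixed before the data were examined, the one for this count matched 354 features and the longer one among the gene lists matched 360.

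**Figure D1:**
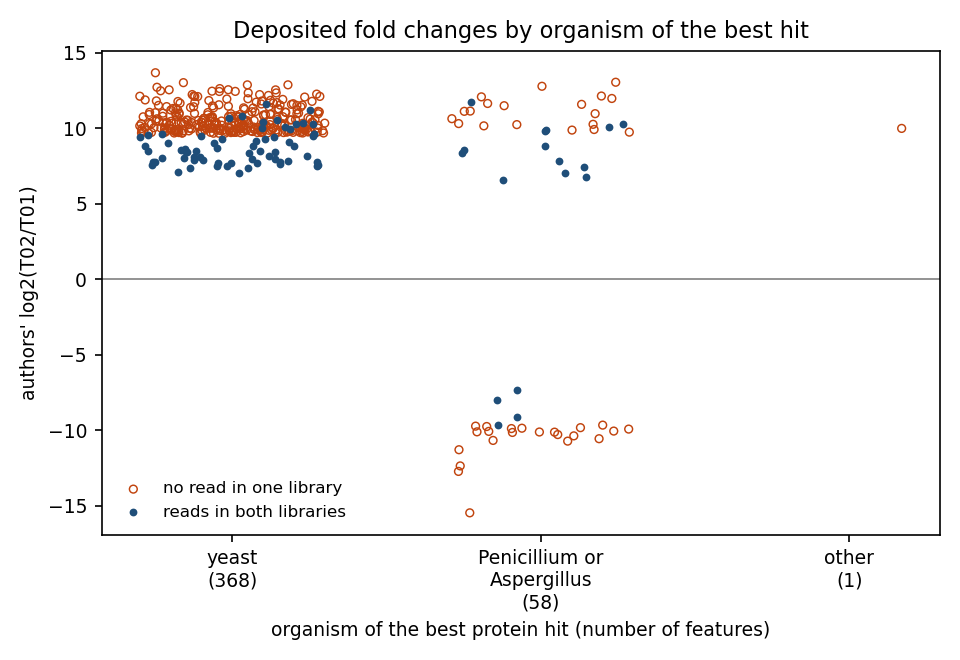
Log2 fold change of T02 over T01 from the authors' deposited table (vertical axis) for each listed feature, grouped by organism of the best protein hit, with 1 point per feature and sideways scatter for legibility. Open points have no recovered read in one of the libraries; all 368 yeast features lie above 0, and the 58 Penicillium or Aspergillus features lie on both sides.

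The deposited fold changes are set in part by a prior count, so whole read numbers were recovered from them. Of the 427 features, 343 had no read in one library. The yeast features had 134 reads in T01 and 155577 in T02 in all, and 301 of the 368 had none in T01. The depth-scaled ratio of these sums was 1268 (exact 95% interval 1070 to 1513, counting error only); it covers features listed because they differed. The median log2 fold change of the yeast features in the authors' deposited table was 10.19, and 6.04 when features without a T01 read were set at a floor of 3 reads in that library. Folds below that are written "at least" use this floor.

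Of the 427 listed features, 368 were yeast features, all higher in T02. Source and direction therefore do not set the yeast members of any list apart. Glycolysis and fermentation had 18 members in the authors' deposited table, of which 15 had a yeast best hit and were higher in T02. This was the highest count of the fixed lists by names and descriptions. With domain and ontology terms also searched, a choice made after seeing the data, proteasome and ubiquitin had 21, and glycolysis and fermentation and cell wall synthesis had 20 each. The recovered reads of the 15 yeast features of glycolysis and fermentation summed to 51 in T01 and 51483 in T02. PGK1, phosphoglycerate kinase, had the highest log2 fold change of the table at 13.67, with no T01 read and 1556 T02 reads, at least 566-fold higher. PYK1, pyruvate kinase, had a log2 fold change of 12.33 in the authors' deposited table and was at least 225-fold higher. All 8 listed members of the tricarboxylic acid cycle and 12 of the 13 of mitochondrial respiration were yeast features higher in T02. ACO1, mitochondrial aconitase, was at least 113-fold higher, and ATP16, the delta subunit of ATP synthase, at least 199.8-fold. The remaining respiration member was a Penicillium feature for the ATP synthase alpha subunit, atp-1, with a log2 fold change of -9.88 in the authors' deposited table. It had 123 reads in T01 and none in T02, at least 37.55-fold lower, and lay in an assembly cluster of 4 features. Both listed sugar transporters were yeast features. KHT2, a hexose transporter, had 6 reads in T01 and 6963 in T02, a ratio of 1267 (exact 95% interval 581.9 to 3454). The ratio of all yeast features together was 1268 (1070 to 1513), so KHT2 does not stand apart from them.

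Stress and membrane lipid genes among the yeast features were also listed as higher in T02, as were all 368 yeast features. All 16 listed heat shock proteins and chaperones had a yeast best hit and were higher in T02. They included KAR2, the chaperone of the endoplasmic reticulum, at least 274-fold higher, HSP12 at least 259.9-fold, and HSP60, the mitochondrial chaperonin, at least 191-fold. All 8 listed members of reactive oxygen defence were yeast features, among them the peroxiredoxin TSA1, with 136 reads in T02 and none in T01. All 9 of the ergosterol list were yeast features, with ERG25 at least 241-fold higher and ERG3 at least 213-fold. Outside the lists, YHB1, the flavohemoprotein that detoxifies nitric oxide, OLE1, the acyl-CoA desaturase, and HEM13, a haem synthesis enzyme, had log2 fold changes of 13.01, 12.54 and 12.48 in the authors' deposited table. A cell surface mannoprotein, MP65, stood at 12.53 in the authors' deposited table. The YHB1, OLE1, HEM13 and MP65 features had no T01 read, so these log2 values rest on the prior count. With the floor they were at least 360-, 259-, 248- and 258-fold higher, in that order.

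**Figure D2:**
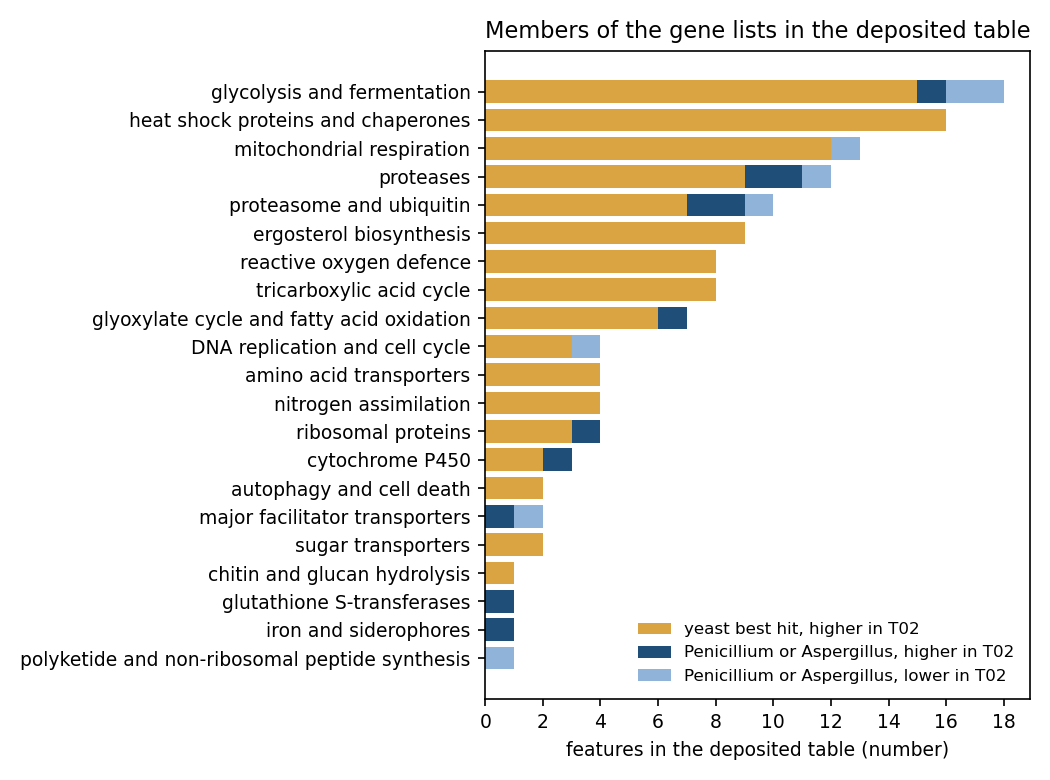
Number of features in the authors' deposited table (horizontal axis) for each fixed gene list with at least 1 member, coloured by organism of the best hit and direction. Glycolysis and fermentation had 18 members and heat shock proteins and chaperones 16, and yeast features made up most of both.

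Among Penicillium and Aspergillus features, 13 higher and 4 lower ones had reads in both libraries. In the authors' deposited table a glutathione S-transferase had the highest log2 fold change of these, 11.71, with 1 read in T01 and 3462 in T02. Its ratio of 3780 had an exact 95% interval of 678 to 149300. A major facilitator transporter had 8 recovered reads in T01 and 2798 in T02, a ratio of 382 (194 to 885). An alcohol dehydrogenase resembling alcA, whose protein hit also names a polyketide synthase enoylreductase domain, was lower in T02. It had 973 reads in T01 and 1 in T02, a ratio of 891 (159.6 to 35230). It was the only listed member of the polyketide and peptide synthesis list. No feature of the patulin list was in the authors' deposited table.

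The other 41 Penicillium and Aspergillus features had reads in 1 library only, 19 in T02 and 22 in T01. A cytochrome P450 resembling stcB had a log2 fold change of 13.04 in the authors' deposited table and was at least 366.5-fold higher. The lowest log2 fold change, -15.46, belonged to a major facilitator transporter with 5879 reads in T01, at least 1795-fold lower in T02. Tryptophan synthase, trp-3, stood at -12.35 and galactokinase, GAL1, at -10.55 in the authors' deposited table. With the floor, trp-3 was at least 208.5-fold lower and GAL1 at least 59.84-fold. Several listed features, all with Penicillium or Aspergillus hits, fell in 1 assembly cluster in 3 cases; in 2 of these they went in opposite directions, and in 1 both were lower in T02. In the authors' deposited table DPP5, dipeptidyl-peptidase 5, was listed at 12.77 and at -12.72, and hxkA, hexokinase, at 12.07 and at -11.28, each pair in 1 assembly cluster. With the floor, the DPP5 features were at least 304.6-fold higher and at least 268.3-fold lower. The hxkA features were at least 187.4-fold higher and at least 99.22-fold lower. The best hit that gave the source of both DPP5 features names a helicase instead, so their peptidase name is uncertain. In the third cluster, both features matched a protein of unknown function; 1 had 7135 reads in T01 and 40 in T02, and the other had 219 and none. All 41 features lay in assembly clusters that hold several features, against 5 of the 17 with reads in both libraries and 9877 of all 20514 identifiers.

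Proteases had 12 members, of which 9 were yeast features, and proteasome and ubiquitin had 10, of which 7 were. The proteases include both DPP5 features, whose protein hits disagree. The glyoxylate cycle and fatty acid oxidation list had 7, with malate synthase, PMS2, at least 123.7-fold higher. The 4 amino acid transporters and the 4 members of nitrogen assimilation were yeast features higher in T02; the last include MET7, a folylpolyglutamate synthase matched by its name only. DNA replication and cell cycle and ribosomal proteins had 4 members each, 3 of them yeast features in either list. Cytochrome P450 had 3 members, 2 of them yeast features, and autophagy and cell death had 2, the yeast features ATG33 and ATG8. Chitin and glucan hydrolysis had 1, the yeast feature BGL2, a glucanase, and iron and siderophores had 1, a Penicillium zinc and iron permease resembling ZRT1 that was at least 174-fold higher. This permease feature had no T01 read and lay in an assembly cluster of 2 features. The pattern missed a yeast feature also named ZRT1, with no T01 read and 426 T02 reads. Of the 28 lists, 7 had no member in the authors' deposited table: patulin biosynthesis, ABC transporters, cell wall synthesis, plant cell wall degradation, conidiation and development, signalling kinases, and zinc cluster transcription factors. These counts reflect the name patterns, and a list without a match is not shown to lack members. Lists with a match can miss members too: the autophagy pattern missed the yeast features described as ATG15 and ATG1. With domain and ontology terms also searched, patulin biosynthesis stayed at 0, while ABC transporters, plant cell wall degradation, signalling kinases and zinc cluster transcription factors had 2 members each, conidiation and development 4 and cell wall synthesis 20. Under that search autophagy and cell death had 6 members, iron and siderophores 9, nitrogen assimilation 9, major facilitator transporters 10, DNA replication and cell cycle 16, glyoxylate cycle and fatty acid oxidation 16, and ergosterol biosynthesis 5. The lowest FDR in the authors' deposited table was 0.0073 and the highest 0.0499, so no listed feature passed an FDR of 0.001.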

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

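Of the alternatives below, the log2 threshold of 2, the FDR threshold of 0.001 and the restriction to M. guilliermondii were planned; the others were chosen after seeing the data. Stricter thresholds and subsets keep fewer features by construction, while wider patterns can add them. A log2 fold change of at least 2 kept all 401 higher and 26 lower features. An FDR under 0.001 left 0 and 0, under 0.03 left 173 and 10, and under 0.02 left 96 and 5. Without yeast best hits 33 higher features were left and all 26 lower ones. With reads in both libraries 80 and 4 were left, and alone in their assembly cluster 291 and 2. The yeast count of 354 was 334 for M. guilliermondii alone, 368 for all yeast genera, 65 with reads in both libraries and 273 alone in their cluster. For Penicillium and Aspergillus the 32 higher and 26 lower features became 25 and 23 for P. expansum alone, 13 and 4 with reads in both libraries, 10 and 2 alone in their cluster, and 10 and 2 under both conditions. When list patterns were also matched to domain and ontology terms, which can add or exclude members, 14 of 28 list counts stayed within 1.5 times and 14 did not; cell wall synthesis went from 0 to 20 and ergosterol from 9 to 5. The planned pseudocounts, level filters and rescalings were not run. They need the values of the T01 and T02 columns, which match no sample and were left out by choice. No paired analysis was possible because there is 1 library per group. Among features without a read in the other library, the lowest recovered number was 97 reads in T02 and 105 in T01. Whether depth or the authors' method set this limit was not examined.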

Other observations

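All tests in this part were chosen after the results were seen, and no explanation by the treatment was tested, since the libraries T01 and T02 match no group. The features named in this paragraph were also chosen after their values were seen. The authors' deposited table has 2 Penicillium features higher in T02 with hits named GliG and GliJ, names of enzymes of gliotoxin synthesis; the first is the glutathione S-transferase with 1 read in T01 and 3462 in T02. The GliJ-type dipeptidase had 2 reads in T01 and 2455 in T02, a ratio of 1340 (exact 95% interval 371 to 11070). A search covered 8 enzyme classes, among them dipeptidases, methyltransferase domains and aromatic prenyltransferases, and was not confined to gliotoxin enzymes. It matched 10 of the 32 Penicillium or Aspergillus features higher in T02 and 2 of the 26 lower ones, both from 1 assembly cluster. The same patterns matched 12 of the 368 yeast features, so the classes are not limited to gliotoxin synthesis. These shares were not tested, since the classes were taken from the features they count. Among the 10 were a pyridine nucleotide-disulfide oxidoreductase with 58 and 17805 reads, a ratio of 335 (259 to 442), and a methyltransferase-domain feature with 18 and 14836 reads, a ratio of 900.0 (569 to 1519). Outside these classes, a CobW-like protein had 91 and 14695 reads, a ratio of 176 (143.5 to 219).

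Yeast best hits among the features higher in T02 may come from RNA of M. guilliermondii, the yeast of the labels, in that library. Of the 368 yeast best hits, 90.8% named that species (exact 95% interval 87.3% to 93.5%), where other yeasts could have been named. P. expansum genes that were merely annotated by a distant yeast were assumed to spread over species, which was not tested. Under that assumption the same 90.8% argues against such annotation as the whole account. P. expansum was itself the best hit of 25 features higher in T02 and 23 lower, so its proteins were among those searched. Without that assumption, this also argues against such annotation, for genes whose P. expansum protein was among them. Neither library was assigned to a group from these values.

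Penicillium and Aspergillus features with reads in 1 library only may be parts of a locus that the assembly divided. Of these, 100% lay in clusters of several features, with a lower limit of 91.4%, against 29.4% (10.3% to 55.96%) of those with reads in both libraries. Of all 20514 identifiers, 48.15% lay in such clusters, and of the yeast features without a T01 read 25.25% (20.44% to 30.55%) did. Only 2 clusters held listed features in opposite directions, and 1 held both a yeast feature and a Penicillium or Aspergillus feature. The latter feature, UBI4, had an Aspergillus fumigatus best hit and is among those with reads in 1 library only. The 100% share cannot tell a divided locus from a whole gene on in 1 library only whose paralog shares its cluster. No conclusion is drawn between them. Paralogs and sequence variants between cultures were not tested and stay open.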
